A study of Homo sapiens with 32 samples.

How the data were processed

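RNA of 11 cultures of the A375 parental line, 11 subcutaneous and 10 lung xenografts was extracted with a column kit, converted to biotinylated cRNA and read on single-colour Affymetrix arrays, per the labels. The deposited values are intensity per probe set on a linear scale (13 to 22091 in 32 arrays), which the authors made with RMA, per the submitters' processing notes. The version of RMA, its settings and whether all arrays were normalized together are not given in the sources used here. RMA gives log2 values, so the linear scale implies a power of 2 taken afterwards, and log2 was taken again before any test. RMA makes arrays alike in distribution, so a change common to all transcripts would not be seen, and probes read background as well as signal, which compresses fold changes of weak genes.

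Of 22283 probe sets, 19071 were annotated to a single gene, 1043 to several and 2169 were not in the annotation, 68 of them control probe sets. Gene names came from the annotation given with the data, and 19059 probe sets matched a gene identifier of the reference genes (assembly GRCh38.p14), which was used only for names and for the order of neighbouring genes. Each of 11963 genes was represented by the probe set with the highest mean over all arrays. No filter on low values was applied, and probe sets without a single gene were left out of the tests.

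Analyses used R 4.3.3, limma 3.58.1 and data.table (1.17.8), and figures used Python 3.11.15 and matplotlib 3.10.9. A linear model with 1 mean for each of 9 combinations (parental cells and 4 lines at each site) was fitted to all 32 arrays, with 23 residual and 3.99 prior degrees of freedom. Limma's moderated tests were two-sided with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05, and counts at a fold of at least 2 were given beside them. Contrasts were unweighted means over lines and sites. Line differences and the interaction of site and line were moderated F tests, and a gene was shared by all 4 lines when each line, averaged over its sites, passed against the parental arrays with the same sign. Shared control arrays were examined by simulation with unchanged groups and by splitting the parental arrays into odd and even replicates.

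A total of 44 gene lists, 8 of them markers of other cell types, was tested with limma's camera at a preset correlation of 0.01, two-sided and adjusted over the lists of a contrast, with estimated correlations and fry as alternatives. List scores are means over members of the log2 difference from the parental mean. Scores of lung and subcutaneous tumours were compared by an exact permutation of sites within lines. Groups, lists, tests, contrasts, the named-gene rule and the main alternatives were fixed before the data were examined.

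Named genes were chosen by rule. For xenografts against parental cells they were the 10 largest rises and 10 largest falls past the threshold with the same sign in all lines and sites, and for lung against subcutaneous tumours the same with the same sign in all 4 lines. For the lines they were the 5 highest F values and the largest rise and fall of each line against the other 3, for the interaction the 3 highest F values, and for each list past the threshold up to 4 members with the largest called change. For markers of other cell types the 2 highest members were taken. ADGRG1, TGM2, RHOC, FN1 and TMSB4X were named whatever their values.

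The steps were tested on simulated data with 11963 genes. Noise was independent between genes and between arrays, with no differences between lines or among parental arrays. The false calls therefore do not give an error rate for the real data. For xenografts against parental cells, 56%, 96%, 100% and 100% of genes changed by 0.25, 0.5, 1 and 2 log2 units were recovered, with 8 false calls, and for lung against subcutaneous tumours 34%, 92%, 98% and 100%, with 6 false calls. Alternatives left out the line from the model, took the line as a random block or line means as replicates, paired tumours by line and letter, used only the groups compared, averaged probe sets, left out IDs ending in _x_at or _s_at, left out the lowest 30% of genes by mean, repeated quantile normalization, centred arrays on their medians, used a trended robust prior or array weights, and left out each array or each line. Added after seeing the data were fits without parental arrays 1 to 5, with the actin and GAPDH 3′ to 5′ differences as covariates, without all 4 xenografts whose nearest array was of the other site, and without MA1 lung A and MA2 subcutaneous A, which were picked by hand from those 4. Other splits of the samples numbered 100 per result.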

Results

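The series measured RNA from the human melanoma cell line A375 and from human tumours grown in mice from metastatic derivatives of that line. Biotin-labelled RNA was read on 32 single-colour Affymetrix arrays. The parental cells, labelled poorly metastatic, gave 11 arrays, which the titles call biological replicates. The derivatives, labelled highly metastatic, gave 11 arrays of subcutaneous tumours and 10 arrays of lung tumours. Tumour titles carry the names MA1, MA2, MC1 and MC2, taken here as 4 derivative lines, each followed by a letter. Line MA1 had 2 subcutaneous and 3 lung arrays, MA2 had 3 and 3, MC1 had 3 and 2, and MC2 had 3 and 2. The labels do not say whether tumours of a line came from separate mice, so p-values measure only the spread between these samples. Parental cells grew in culture and derivatives in mice, so the labelled metastatic ability and the place of growth changed together and the series cannot separate them. The 75th percentile of intensity averaged 249 ± 12.4 (SD, n = 11) in parental cells, 231 ± 7.24 (SD, n = 11) in subcutaneous tumours and 234 ± 5.98 (SD, n = 10) in lung tumours. The number of arrays limits the precision.

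Parental and tumour arrays lay apart on the first principal component of the 2000 most variable genes, which held 60% of their variance, and the second held 9.31%. All 11 parental arrays were closest to another parental array. Of the 21 xenografts, 17 were closest to an array of their own site and 13 to an array of their own line. An axis was drawn through 589 genes chosen without MA1, with the parental mean at 0 percent and the mean of lines MA2, MC1 and MC2 at 100 percent. Both MA1 subcutaneous tumours stood apart at 48.8 and 50 percent, and the other 19 xenografts spanned 82.5 to 107 percent. Tumours of MA2, MC1 and MC2 define the axis, so their place near 100 percent is built in. The MA1 lung tumours, which do not define it, lay at 82.5, 98.4 and 102 percent. Parental arrays 1 to 5 lay at -15.4 to -4.79 percent, with a 75th percentile of intensity of 257 to 268, and arrays 6 to 11 at 3.1 to 11.6 percent, with 234 to 244. The difference between 3′ and 5′ actin control probe sets, a sign of RNA quality, averaged 0.18 ± 0.46 log2 units (SD, n = 11) in parental cells, -0.11 ± 0.25 (SD, n = 11) in subcutaneous tumours and -0.26 ± 0.21 (SD, n = 10) in lung tumours.

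**Figure D1:**
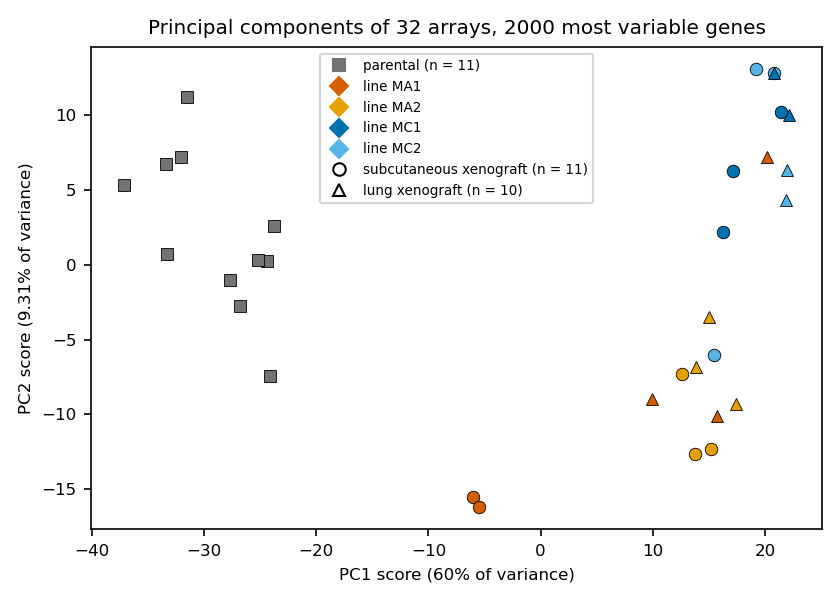
Scores of the 32 arrays on the first and second principal components of the 2000 most variable genes, on the log2 scale, coloured by line and shaped by group. On the first component the 2 MA1 subcutaneous tumours lie between the 11 parental arrays and the other 19 xenografts. On the second they have the lowest scores of all arrays, -15.5 and -16.2.

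The first comparison asked how tumours grown from the metastatic derivatives differed from the parental cell line, which is the contrast the series names. ENPP2, which encodes the secreted lysophospholipase autotaxin, rose 28.1-fold, a log2 change of 4.81 ± 0.30 (SE, n = 21 and 11). RGS5, a regulator of G-protein signalling, rose 20.7-fold (4.37 ± 0.16), and the protease inhibitor A2M rose 16.1-fold (4.01 ± 0.18). CHRNA9, an acetylcholine receptor subunit, fell by 4.83 ± 0.15 on the log2 scale, and COL6A3, a collagen VI chain, fell by 4.14 ± 0.34. NT5E, the surface enzyme that makes adenosine from AMP, fell by 4.10 ± 0.17.

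Among the other genes with the largest rises, the matrix proteins MGP and DCN changed by 3.87 and 3.76 log2 units. GPM6B, ROPN1B, CPN1, GPNMB and FXYD3 rose by 3.54, 3.52, 3.39, 3.37 and 3.24. Among the largest falls, NPTX2 changed by -3.74, TFPI2, an inhibitor of coagulation proteases, by -3.64 and S100A2 by -3.41. The semaphorin and VEGF receptor NRP1 fell by 3.36, the transcription factor SOX9 by 3.35 and the p53 target PERP by 3.31. PHLDA2 fell by 3.48 on 1 of its 2 probe sets, and the other, used when IDs ending in _x_at or _s_at were left out, gave 0.07 (adjusted p = 0.123). All 20 passed the threshold in the same direction in each of the 4 lines, which was largely fixed by choosing genes with the same sign in all lines and the largest changes. ENPP2 averaged 6.02 ± 1.11 (SD, n = 11) in parental cells and 10.94 ± 1.43 (SD, n = 11) in subcutaneous tumours, so its spread between arrays was smaller than the difference.

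**Figure D2:**
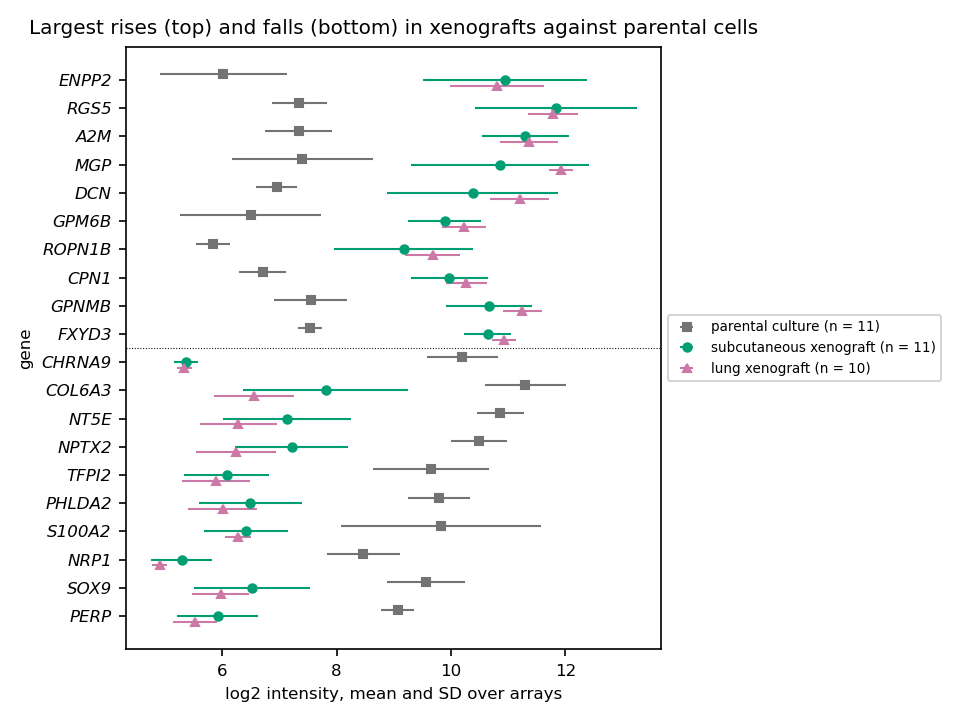
Mean log2 intensity with SD of the 10 genes with the largest rises and the 10 with the largest falls, in parental cells (n = 11), subcutaneous tumours (n = 11) and lung tumours (n = 10). ENPP2 changed by 4.81 and CHRNA9 by -4.83 log2 units.

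Across 11963 genes, 4296 rose and 3151 fell at an adjusted p under 0.05, which is 62.3% of the genes, with 199 and 316 of them at least 2-fold. The same sign in all 8 combinations of line and site was found for 5710 of the called genes. The median change of all genes was 0.06, and the higher share of calls, 57.7%, became 46.1% when each array was centred on its median. Leaving out parental arrays 1 to 5, an alternative chosen after seeing the data, left 1818 higher genes, and adding the actin and GAPDH 3′ to 5′ differences as covariates left 1895. With the 4 line means, each averaged over both sites, as the replicates against single parental arrays, 1704 genes rose and 1938 fell. Of these 3642, 3641 were among the genes called with single tumours as replicates.

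Genes of melanoma cell state moved in opposite directions. Of 21 measured invasive or dedifferentiated melanoma genes, 15 fell, 4 rose and 2 were not called, with 16 falls and 4 rises adjusted over the list alone (adjusted p = 3.29e-06 by camera, adjusted p = 0.0388 with an estimated correlation). The chemokine CXCL8 fell by 2.40 ± 0.26 and INHBA by 2.23 ± 0.34, although INHBA gave -0.09 (adjusted p = 0.163) when IDs ending in _x_at or _s_at were left out. Of 20 melanocyte differentiation genes, 15 rose, 2 fell and 3 were not called, with the same counts of 15 and 2 adjusted over the list alone (adjusted p = 0.00129, adjusted p = 0.0847 with an estimated correlation). The melanocyte transcription factor MITF rose by 2.48 ± 0.13 and the endothelin receptor EDNRB by 1.71 ± 0.11. Among 18 neural crest and stem-like genes, 11 rose, 3 fell and 4 were not called, and 11 and 3 adjusted over the list alone (adjusted p = 0.0433, adjusted p = 0.137 with an estimated correlation). RXRG rose by 3.00 ± 0.17, and S100B by 2.06 ± 0.13, TFAP2B rose 3.99-fold, and SOX9, also in this list, fell. ERBB3 rose by 2.31 ± 0.13 on 1 of its 2 probe sets and gave 0.04 (adjusted p = 0.514) without IDs ending in _x_at or _s_at.

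**Figure D3:**
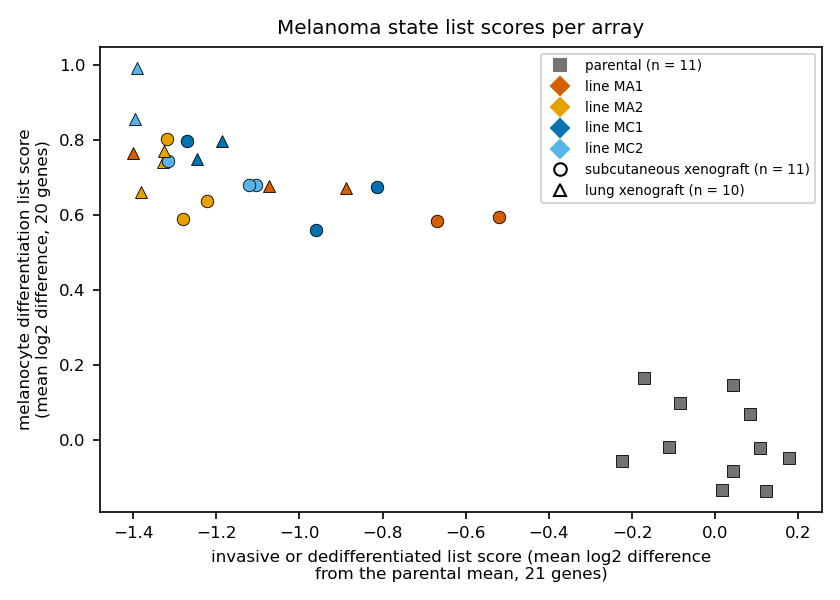
Score of the invasive or dedifferentiated list (21 genes) against that of the melanocyte differentiation list (20 genes) for each of the 32 arrays, as mean log2 differences from the parental mean. Invasive scores averaged -1.05 in subcutaneous and -1.26 in lung tumours, and melanocyte scores 0.667 and 0.768.

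Cell cycle, core histone, heat shock, hypoxia and glycolysis lists were lower in tumours. Of 31 cell cycle and mitosis genes, 24 fell, 2 rose and 5 were not called, with 25 and 2 adjusted over the list alone (adjusted p = 3.01e-06, adjusted p = 0.366 with an estimated correlation). MAD2L1, a spindle checkpoint gene, fell by 1.34 ± 0.16, TTK by 0.79 ± 0.10 and PRC1 by 0.73 ± 0.08, and BUB1 fell by 0.77 ± 0.11 on 1 of its 5 probe sets. Cell cycle scores were 0.107 to 0.325 in parental arrays 1 to 5 and -0.244 to 0.0241 in arrays 6 to 11. Lung tumours, at -0.655 to -0.107, overlapped the latter, and subcutaneous tumours had -0.661 to -0.272. Heat shock scores also differed among parental arrays, at -0.00738 to 0.244 in 1 to 5 and -0.282 to 0.0837 in 6 to 11. Among 11 core histones, 6 fell, 0 rose and 5 were not called, the same adjusted over the list alone (adjusted p = 0.0305, adjusted p = 0.366 with an estimated correlation), including H2AC6 at -1.19 ± 0.16. Heat shock proteins gave 9 falls, 1 rise and 1 member not called of 11, with 9 and 1 adjusted over the list alone (adjusted p = 0.0111, adjusted p = 0.366 with an estimated correlation), and the co-chaperone BAG3 fell by 1.02 ± 0.08. Of 25 hypoxia genes, 13 fell, 3 rose and 9 were not called, and 13 and 3 adjusted over the list alone (adjusted p = 0.00822, adjusted p = 0.495 with an estimated correlation). STC1 fell 4.01-fold, and P4HA2 changed by -1.11 ± 0.12 and ADM by -1.10 ± 0.20. Glycolysis genes gave 7 falls, 2 rises and 7 members not called of 16, with 7 and 2 adjusted over the list alone (adjusted p = 0.0247, adjusted p = 0.513 with an estimated correlation), and ENO2 fell by 1.51 ± 0.15. The 2 MA1 subcutaneous tumours showed no fall in hypoxia scores (0.169 and 0.127) or glycolysis scores (0.152 and 0.188), where the other 19 xenografts were all below 0, and ENO2 averaged 9.42 in them and 9.35 in parental cells.

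Lists of TGF-beta and BMP targets, p53 targets and NF-kB targets also fell. Among 20 TGF-beta and BMP targets, 12 fell, 4 rose and 4 were not called, with 12 and 4 adjusted over the list alone (adjusted p = 0.00319, adjusted p = 0.0847 with an estimated correlation). PMEPA1 fell by 2.37 ± 0.20, ID1 by 2.18 ± 0.19 and TGFBI by 1.78 ± 0.07. In the 2 MA1 subcutaneous tumours the TGF-beta and BMP scores were 0.0213 and 0.0584, against -0.967 to -0.419 in the other 19 xenografts, and ID1 averaged 10.71, against 10.40 in parental cells. Of 20 p53 targets and apoptosis genes, 11 fell, 3 rose and 6 were not called, and 11 and 3 adjusted over the list alone (adjusted p = 0.00985, adjusted p = 0.128 with an estimated correlation). PMAIP1 fell by 2.79 ± 0.13 and CDKN1A by 1.14 ± 0.11. MCL1 fell by 0.87 ± 0.11 and gave 0.105 (adjusted p = 0.601) without IDs ending in _x_at or _s_at. The NF-kB, cytokine and chemokine list had 13 falls, 5 rises and 5 members not called of 23, with 13 and 6 adjusted over the list alone (adjusted p = 0.0282, adjusted p = 0.366 with an estimated correlation), and LIF fell by 1.19 ± 0.11.

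Interferon-stimulated genes gave 23 rises, 2 falls and 7 members not called of 32, and 24 and 2 adjusted over the list alone (adjusted p = 0.00146, adjusted p = 0.513 with an estimated correlation). BST2 rose by 2.10 ± 0.37 and IFI27 by 2.04 ± 0.44. Lists of markers of other cell types were also higher in the tumours, which does not show that such cells were present. Of 18 fibroblast and pericyte markers, 9 lay above the median gene in the parental culture, and 6 were also in another list. Above that median lay only 2 of 19 endothelial, 2 of 16 lung epithelial and 3 of 8 erythroid markers, so most of these were weak. Of 18 fibroblast and pericyte markers, 12 rose, 2 fell and 4 were not called, with 12 and 2 adjusted over the list alone (adjusted p = 0.0339, adjusted p = 0.174 with an estimated correlation), RGS5 and DCN among them. CSPG4 rose by 1.21 ± 0.15 and LUM by 1.03 ± 0.11. All 8 erythroid markers rose, also adjusted over the list alone (adjusted p = 0.0247, adjusted p = 0.513 with an estimated correlation), with HBB at 0.43 ± 0.08. Of 16 lung epithelial markers, 9 rose, 0 fell and 7 were not called, the same adjusted over the list alone (adjusted p = 0.0292, adjusted p = 0.513 with an estimated correlation), and SFTPC rose from 7.83 to 8.18 in subcutaneous and 8.29 in lung tumours. Endothelial markers gave 12 rises, 1 fall and 6 members not called of 19, the same adjusted over the list alone (adjusted p = 0.0433, adjusted p = 0.513 with an estimated correlation), with KDR at 0.41 ± 0.08. Calls for 3 of these lists ended without parental arrays 1 to 5 (endothelial 0.163, lung epithelial 0.253 and erythroid 0.126) and with the RNA quality covariates (0.103, 0.0716 and 0.0589).

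The remaining marker lists did not pass. Of 23 macrophage and leukocyte markers 9 rose and 0 fell, with the same 9 and 0 adjusted over the list alone (adjusted p = 0.0975, adjusted p = 0.614 with an estimated correlation). Adipocyte markers gave 7 rises and 1 fall of 12, the same adjusted over the list alone (adjusted p = 0.128, adjusted p = 0.513 with an estimated correlation), and LPL rose by 2.42 ± 0.13. Skeletal muscle markers gave 7 rises and 1 fall of 19, with 6 and 1 adjusted over the list alone (adjusted p = 0.297, adjusted p = 0.7 with an estimated correlation). Keratinocyte and skin markers gave 6 rises and 2 falls of 15, with 5 and 2 adjusted over the list alone (adjusted p = 0.745, adjusted p = 0.94 with an estimated correlation).

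Genes named in earlier work on A375 metastasis did not share a direction. ADGRG1, an adhesion receptor also called GPR56, fell by 2.48 ± 0.19 and was lower in all 4 lines. Its reported binding partner, the transglutaminase TGM2, rose by 0.32 ± 0.10 (adjusted p = 0.00978), and gave 0.05 (adjusted p = 0.694) without parental arrays 1 to 5. The actin-binding peptide TMSB4X fell by 0.67 ± 0.15. RHOC, like TGM2, TMSB4X and FN1, passed neither higher nor lower in all 4 lines. Fibronectin, FN1, fell by 1.41 ± 0.22 on 4 of its 6 probe sets and gave -0.01 (adjusted p = 0.804) without IDs ending in _x_at or _s_at. Of the 14 genes on that list, 5 rose, 5 fell and 4 were not called, the same adjusted over the list alone, and the median (0.03), mean (-0.00319) and test direction (lower) differed in sign (adjusted p = 0.689, adjusted p = 0.87 with an estimated correlation).

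The next comparisons took each site against the same parental arrays. Subcutaneous tumours gave 3787 higher and 2923 lower genes, 168 and 282 of them at least 2-fold, and lung tumours gave 3488 higher and 2840 lower genes, 240 and 351 at least 2-fold. The higher share of calls, 56.4% and 55.1%, became 44.8% and 43.4% after centring each array on its median. The invasive list fell at both sites, with 13 of 21 members lower in subcutaneous tumours (14 adjusted over the list alone, adjusted p = 1.64e-05, adjusted p = 0.0668 with an estimated correlation) and 15 in lung tumours (15 adjusted over the list alone, adjusted p = 4.51e-07, adjusted p = 0.0204 with an estimated correlation). The melanocyte list rose at both, with 13 of 20 members higher in subcutaneous tumours (13 adjusted over the list alone, adjusted p = 0.00404, adjusted p = 0.0856 with an estimated correlation) and 14 in lung tumours (14 adjusted over the list alone, adjusted p = 0.000271, adjusted p = 0.0471 with an estimated correlation). Interferon-stimulated genes gave 8 rises and 3 falls of 32 in subcutaneous tumours (6 and 3 adjusted over the list alone, adjusted p = 0.908, adjusted p = 0.973 with an estimated correlation), where the median was 0.05 and the mean -0.0021, and 27 rises and 1 fall in lung tumours (the same adjusted over the list alone, adjusted p = 5.69e-09, adjusted p = 0.352 with an estimated correlation). In all, 15 of 44 lists passed in each, and with an estimated correlation 0 passed in subcutaneous and 2 in lung tumours. Both comparisons called 2788 genes higher and 2442 lower, against 1104 and 694 for independent lists of these sizes. When odd and even parental arrays served 1 comparison each, 1510 and 1946 were called in both. Those lists came from fewer parental arrays and have other sizes, so 1104 and 694 are not their expected overlap. The log2 changes correlated across genes at 0.943, at 0.89 with the parental arrays split, and at 0.479 in simulated groups with no change, where genes are not independent replicates. Without parental arrays 1 to 5, 1637 genes were higher in subcutaneous and 1581 in lung tumours.

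The comparison of lung with subcutaneous tumours of the same lines asked what the site of growth changed. Interferon-stimulated genes were higher in lung tumours. IFI27 rose 14.3-fold, a log2 change of 3.83 ± 0.52 (SE, n = 10 and 11), and ISG15, a ubiquitin-like protein, rose 7.09-fold (2.83 ± 0.34). BST2, IFIT1, MX1 and IFI44L rose by 2.25, 2.24, 1.86 and 1.53. Of 32 members, 25 rose, 0 fell and 7 were not called, with 28 and 1 adjusted over the list alone (adjusted p = 2.98e-53, adjusted p = 0.00471 with an estimated correlation). The mean score of the list was 0.886 ± 0.839 (SD, n = 10) in lung and 0.014 ± 0.294 (SD, n = 11) in subcutaneous tumours, against an SD of 0.228 in parental cells. The lung minus subcutaneous difference was 1.02, higher in 4 of 4 lines (0.202 to 1.8), with p = 6e-04 by a two-sided exact permutation test within lines over 20000 arrangements, and 0.0264 adjusted over 44 lists, of which no other passed this test. Scores of 6 of the 10 lung arrays exceeded every subcutaneous array.

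**Figure D4:**
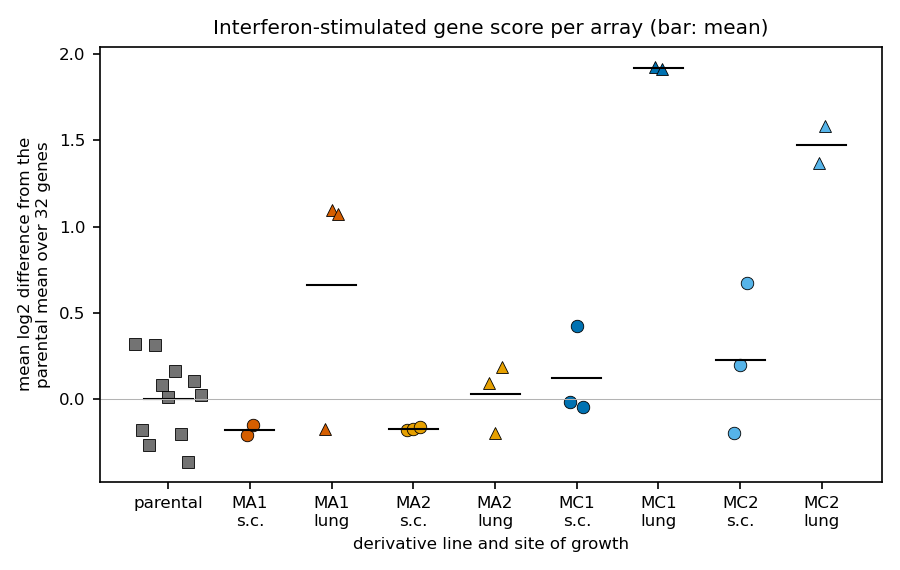
Interferon-stimulated gene score of each array, the mean log2 difference from the parental mean over 32 genes, by line and site, with bars at the means. Lung means were 1.92 in MC1, 1.47 in MC2, 0.664 in MA1 and 0.0287 in MA2.

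Other genes with large rises in lung tumours were the matrix proteoglycan LUM (1.69 ± 0.13), the antioxidant enzyme GPX3 (1.66 ± 0.39), the embryonic globin HBE1 (1.65 ± 0.29, on 1 of 2 probe sets) and the stress cytokine GDF15 (1.64 ± 0.21). Genes with large falls were FN1 (-1.37 ± 0.27), NPTX2 (-1.20 ± 0.22), the receptor kinase AXL (-1.09 ± 0.18), NT5E (-1.09 ± 0.20), CRYBG1 (-1.08 ± 0.15) and the phosphate transporter SLC20A1 (-1.08 ± 0.17). HS3ST3A1, SMURF2, AIM2 and EMP1 fell by 1.02, 0.96, 0.94 and 0.93. Without line MA1 the calls for NPTX2, AXL, NT5E, HS3ST3A1, AIM2 and EMP1 ended, without MC2 those for GPX3 and FN1, without MC1 those for BST2 and GPX3, and without IDs ending in _x_at or _s_at those for GDF15 and FN1. The EMP1 call also ended with many of the single arrays left out. MHC class I and antigen processing genes gave 8 rises, 0 falls and 5 members not called of 13, with 10 and 1 adjusted over the list alone (adjusted p = 3.79e-12, adjusted p = 0.0854 with an estimated correlation), and the immunoproteasome subunit PSMB9 rose by 0.68 ± 0.11, HLA-F and HLA-G by 0.64 ± 0.11 each. The list score was higher in 2 of 4 lines (-0.0433 to 1.04), with a two-sided exact permutation p of 0.0226 that became 0.142 over 44 lists. The HLA-F call ended without MC1 and without IDs ending in _x_at or _s_at, and the HLA-G call without MC1.

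**Figure D5:**
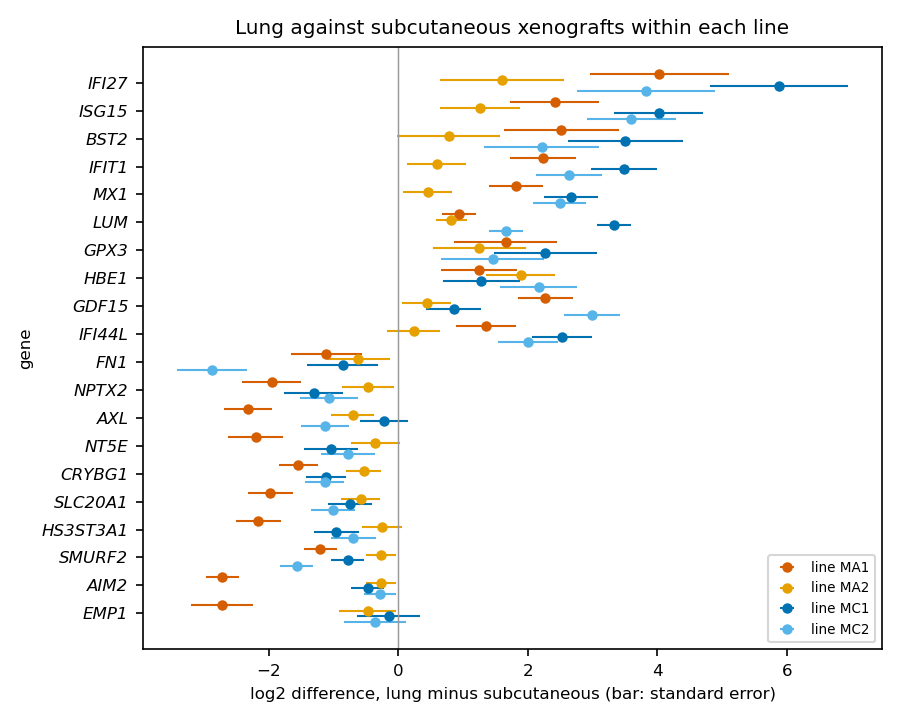
Log2 difference of lung minus subcutaneous tumours in each line, with its standard error, for the 10 genes with the largest rises and the 10 with the largest falls. The IFI27 difference was 5.88 in MC1 and 1.60 in MA2.

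Of the invasive list 3 members fell, 1 rose and 17 were not called in lung against subcutaneous tumours, with 8 and 1 adjusted over the list alone (adjusted p = 0.000859, adjusted p = 0.139 with an estimated correlation), and TGFBI fell by 0.37 ± 0.08. The melanocyte list had 2 rises, 1 fall and 17 members not called, with 5 and 1 adjusted over the list alone (adjusted p = 0.0152, adjusted p = 0.282 with an estimated correlation), and APOE rose by 0.38 ± 0.08 and MLANA by 0.25 ± 0.06. The APOE call ended without MA1 or MC2, the MLANA call without MC1 or MC2, and the TGFBI call without MC2. The score differences were -0.253 and 0.121, in the same direction in 4 of 4 lines, and the two-sided exact permutation p of 0.0029 and 0.0036 became 0.0528 each over 44 lists. Oxidative phosphorylation genes gave 2 rises of 27, CYC1 and ATP5MC1, and 9 adjusted over the list alone (adjusted p = 4.19e-06, adjusted p = 0.389 with an estimated correlation). Fatty acid synthesis gave 1 rise of 10, FADS2, and 5 adjusted over the list alone (adjusted p = 0.0072, adjusted p = 0.328 with an estimated correlation). Cholesterol synthesis gave 1 rise of 17, SQLE, also adjusted over the list alone (adjusted p = 0.0108, adjusted p = 0.389 with an estimated correlation). The calls for CYC1, ATP5MC1, FADS2 and SQLE each ended without MA1, MC1 or MC2. Cell cycle genes passed upward with 0 of 31 members called by limma, 14 higher at an unadjusted p under 0.05 and 4 adjusted over the list alone (adjusted p = 1.88e-08, adjusted p = 0.389 with an estimated correlation). DNA replication had 0 of 29 called by limma, 6 higher and 1 lower unadjusted, and 0 adjusted over the list alone (adjusted p = 0.0108, adjusted p = 0.6 with an estimated correlation). Skeletal muscle markers passed downward with 0 of 19 called by limma, 1 lower unadjusted, and 0 adjusted over the list alone (adjusted p = 0.0223, adjusted p = 0.551 with an estimated correlation).

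Of the fibroblast and pericyte markers 3 rose between the sites (LUM, DCN by 1.12 ± 0.18 and ACTA2 by 0.49 ± 0.11), 1 fell (S100A4, -0.63 ± 0.15) and 14 were not called, with 3 and 2 adjusted over the list alone (adjusted p = 0.191, adjusted p = 0.418 with an estimated correlation). Their score difference was 0.114, higher in 4 of 4 lines (two-sided exact permutation p = 0.0172, adjusted 0.142 over 44 lists). The lung epithelial, leukocyte, endothelial and erythroid lists had no called members, and adjusted over the list alone 1 endothelial marker was higher and 0 of the other lists differed. Limma called 0 of 16 lung epithelial markers (2 higher and 2 lower unadjusted, score difference 0.00612), 0 of 23 leukocyte markers (0 and 2, -0.0103), 0 of 19 endothelial markers (1 and 0, 0.000712) and 0 of 8 erythroid markers (2 and 0, 0.0467). Of the 11963 genes, 191 rose and 98 fell in lung against subcutaneous tumours, which is 2.42%, with 23 and 7 at least 2-fold and 216 with the same sign in all 4 lines. This count rested on treating tumours of a line as replicates. With line means as replicates limma called 0 genes (890 at an unadjusted p under 0.05), with the line as a random block 30 rose and 5 fell, and without the line in the model 12 rose and 3 fell. Pairing tumours by line and letter gave 0 genes (1537 unadjusted). The 9 pairs correlated at -0.232 to 0.193, which does not settle whether letters pair tumours, and the labels do not say. Single arrays moved the count. Higher genes numbered 123 without MA1 subcutaneous B and 351 without MC2 subcutaneous C. Lower genes numbered 50 without MA1 subcutaneous B, 54 without MC1 lung B, 57 without MC2 lung A, 58 without MC2 lung B, 65 without MC1 subcutaneous C, and 156 without either MC1 subcutaneous B or MC2 subcutaneous C.

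The lines were then compared with each other over both sites. MA1 tumours held more AIM2, a sensor of cytosolic DNA, than the other 3 lines (1.70 ± 0.15, SE) and less of the surface glycoprotein CD200 (-1.58 ± 0.14). MA1 also had higher PCLO (1.05 ± 0.09), S100A13 (1.19 ± 0.11) and INHBA (2.24 ± 0.47), and lower MGP (-1.93 ± 0.41). The 2 MA1 subcutaneous tumours carried most of these differences. Their means were 9.90 for AIM2, 6.06 for CD200, 6.96 for PCLO, 12.4 for S100A13, 10.58 for INHBA and 7.82 for MGP, against 7.18, 8.31, 4.86, 11.18, 7.28 and 11.83 in MA1 lung tumours. MA2 had more of the collagen COL11A1 (3.98 ± 0.51) and less IFI27 (-2.34 ± 0.57). MC1 had more PLAAT4 (0.93 ± 0.08) and more of the water channel AQP1 (2.27 ± 0.44), and less COL11A1 (-2.13 ± 0.55). COL11A1 was 9.81 in MA1 lung B and 8.77 in MC2 subcutaneous A, near its MA2 means of 8.87 and 9.35. In MC2 the endothelin EDN3 was lower (-2.14 ± 0.49), and IFI27 differed by 2.05 ± 0.61 (adjusted p = 0.0667). A moderated F test called 1321 genes, 261 of them at least 2-fold, and each line against the other 3 gave 694 genes in MA1, 391 in MA2, 394 in MC1 and 365 in MC2. Interferon-stimulated genes made up 25 of these calls and MHC class I genes 10. Without line MA1 the F test called 746 genes, and without MA2 808.

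Site effects that differed among lines were tested for each gene. In MA1, PCLO fell by 2.11 ± 0.15 from subcutaneous to lung tumours (over all lines the fall was called on 1 of its 3 probe sets), and the matrix phosphoprotein SPP1 rose by 2.72 ± 0.22 and TBC1D4, a regulator of glucose transport, by 2.18 ± 0.21. The same differences in MC2 were 0.01 ± 0.15, -0.59 ± 0.22 and -0.46 ± 0.21, none past the threshold. The F test of the difference called 100 genes, among them 7 interferon-stimulated and 5 MHC class I genes. For 88 of the 100 the site effect differed at least 2-fold between some lines. Lung against subcutaneous counts within lines were 102 higher and 146 lower genes in MA1, 1 and 0 in MA2, 77 and 7 in MC1, and 83 and 84 in MC2. Interferon-stimulated genes called higher in lung numbered 5 in MA1, 24 in MC1 and 15 in MC2, and 0 in MA2 by limma (0 at an unadjusted p under 0.05). The count of 100 depended on single tumours. It was 48 without MA1 subcutaneous B, 53 without MA1 subcutaneous A, 62 without MC1 lung C, 65 without MC2 lung A, 164 without MA1 lung C, 174 without MC2 subcutaneous C and 431 without MC1 subcutaneous B.

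Changes shared by the lines were counted by testing each line against the parental arrays. All 4 lines called 1014 genes higher and 1425 lower, with 92 and 157 at least 2-fold. Of the invasive list 11 members were lower in all 4 lines and 1 was higher, and of the melanocyte list 8 were higher and 0 lower by limma. Cell cycle genes gave 13 lower and 1 higher, and interferon-stimulated genes 1 and 4. Separately, MA1 gave 2187 higher and 2106 lower genes, MA2 2855 and 2352, MC1 2454 and 2513, and MC2 3194 and 2796. The lines shared the same controls. Independent lists of these sizes would share 28.6 higher and 20.3 lower genes. In 20 simulations with unchanged groups at most 0 genes were shared, but unchanged lines have few calls to share. Odd parental arrays alone gave 1048 and 1409, and even ones gave 630 and 1106. In each of these fits the lines still shared their controls, so the part of the overlap due to shared controls was not measured. Without MA1 subcutaneous B 666 genes were higher in all 4, without parental arrays 1 to 5 488 were higher and 831 lower, and with the RNA quality covariates 465 and 860. Without the 4 xenografts whose nearest array was of the other site, 543 genes were higher in all 4 lines.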

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

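Tests chosen after the result was seen were those of the MA1 subcutaneous tumours, the single-line test of the interferon genes and both tests of xenografts closest to another line, while the tests on host cells, on RNA quality for the interferon genes and on other splits were set beforehand.

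Both MA1 subcutaneous tumours lay at 48.8 and 50 percent of the way from parental cells to the xenografts of the other lines. If parental cells had been mixed in, linear shares of the parental and xenograft profiles would add to about 1. The sums averaged 0.459 and reached at most 0.476. They lay below the 0.637 to 1.39 of the other 19 xenografts and the 0.651 to 1.31 of the parental arrays, which argues against it. The sums of these other arrays spread widely around 1, so the measure is rough. That test replaced an undecided one, which counted genes over 1 log2 unit outside all other arrays and found 4 in MA1 subcutaneous tumours against at most 3 in another line and site. The highest parental array lay at 11.6 percent, which argues against a swap with parental cells, and the actin difference of 2 of the 2 tumours, -0.207 and -0.244, lay within the -0.518 to 0.271 of the other xenografts, which argues against RNA quality as read by that probe. A difference of these tumours themselves stays open, was not tested, and may be biological only as a hypothesis.

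Interferon-stimulated genes rose in lung tumours. At least 15 members were called when any 1 line was left out, against 25 with all lines, which argues against a single line as the whole source, and 24 members were called with the RNA quality covariates, which argues against RNA quality. RNA from host lung or blood could not be decided: across the 10 lung arrays the interferon score had Pearson r 0.0935 with host markers (permutation p = 0.801, adjusted 0.801 over 3 relations) and Spearman rho 0.321 (permutation p = 0.369), and r was 0.636 without the 2 arrays farthest from the median, while probes for human genes read mouse RNA to an unknown extent. A response of the tumour cells to the lung stays open as a hypothesis. No member was called with line means as replicates or in pairs by letter (0 each).

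Assigned by 200 line-specific genes from the other arrays, 8 of 21 xenografts fell to another line. More alike actin differences went with closer arrays at a Mantel r of -0.0862 (permutation p = 0.0913), so RNA quality cannot be told apart at this size. In 2 pairs of lines, MA1 with MA2 and MC1 with MC2, arrays lay in each other's line, as wrong labels would need, but how often such partners arise by chance was not tested, so wrong labels stay open, as do lines with similar profiles. This reading was set after the result was seen.

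Splits of the samples into other groups of the same sizes, 100 for each result, tested whether the counts could arise by chance. In xenografts against parental cells only the real split reached 7447 genes, and the highest other gave 2490. The same held for subcutaneous tumours (6710, highest other 4451), lung tumours (6328, 197), the lines (1321, 194) and all 4 lines (2439, 0). Single arrays were shuffled, although tumours belong to lines. The splits therefore show that random regrouping of arrays did not reach these counts, and do not measure chance differences between lines. For lung against subcutaneous tumours 2 splits, counting the real one, reached 289 genes. The share was under 0.05, but the highest other, 332, exceeded the real count, and the reason was not tested. For the interaction 5 splits, counting the real one, reached 100 genes and the highest other gave 201, so chance was not excluded.

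Far arrays were found in 18 of 172 checks of the lung tumours, as the gap to the nearest array divided by the range, where chance gives about 1 in 20. For MA1 lung A the value was 0.485 for the fatty acid synthesis score, 0.505 for COL6A3, 0.721 for SOX9 and 0.507 for MYL11. For MA1 lung C it was 0.49 for NT5E, 0.587 for PERP, 0.674 for AIM2, 0.53 for INHBA, 0.497 for LIF, 0.621 for MCL1 and 0.744 for H1-2, and for MA1 lung B 0.576 for FSCN1. MA2 lung B gave 0.479 for ACTN1 and 0.511 for PFKP, MC1 lung B 0.61 for NFKBIA, MC1 lung C 0.514 for the adipocyte score and 0.611 for KDR, and MC2 lung B 0.538 for TEK.

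The site effect differed among lines for 16 of 128 named genes by limma's interaction test, against 100 of all 11963 genes. Part of the 16 was fixed by selection. PCLO, SPP1 and TBC1D4 were named for the highest interaction F values, and others for differences between lines. For the count of 100 genes, splits of the samples did not exclude chance. Adjusted p was 1.3e-06 for PCLO, 1.4e-06 for SPP1, 3.1e-05 for TBC1D4, 0.00027 for PLAAT4, 3e-04 for AIM2, 0.00042 for CD200, 0.00048 for LUM and 0.0014 for RGS5. It was 0.0018 for HLA-G, 0.0043 for DCN, 0.0057 for ID1, 0.0059 for ROPN1B, 0.0068 for HLA-F, 0.026 for HLA-B, 0.03 for LPL and 0.048 for GDF15. Among 3150 probe sets without a single gene, which no comparison used, 1762 passed between xenografts and parental cells, 23 at least 2-fold higher and 37 lower.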

How the results depend on the processing

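The fits without parental arrays 1 to 5, with RNA quality covariates, without the 4 xenografts nearest to the other site and without MA1 lung A and MA2 subcutaneous A, picked by hand from those 4, were chosen after the result was seen. Of 622 recomputed counts 540 stayed within 1.5 times and 82 moved. Values of 97 named genes in xenografts against parental cells and 31 in lung against subcutaneous tumours were recomputed, mostly in fits without 1 array. Many of these genes were chosen for large changes. Sign changes of genes called in neither fit counted as kept. Against parental cells 4746 values were kept, 57 lost their call, 7 gained one and 2 reversed. The reversals were PHLDA2 (0.0658) and MCL1 (0.105) without IDs ending in _x_at or _s_at, where other probe sets represent the genes. In lung against subcutaneous tumours 1330 were kept and 270 lost their call. List tests gave 458 kept, 40 lost and 30 gained. Probes near background limit what weak genes show. Unless stated, the cause was not tested.

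Lung against subcutaneous counts were 12 higher and 3 lower without the line in the model, 30 and 5 with the line as a random block, 0 and 0 with line means (fewer replicates), 0 and 0 in blocks of line and letter, 634 and 487 with array weights, 94 and 29 without line MA1, 96 higher without MC1, 62 lower without MC2, 157 lower with only the groups compared and 94 higher without IDs ending in _x_at or _s_at. Leaving out each array gave 123 to 351 higher and 50 to 156 lower. The interaction count was 158 with only the groups compared, 42 without those IDs, 1383 with array weights, 33 without MA1, 167 without parental arrays 1 to 5, and 48 to 431 leaving out each array. The lines count was 755 without those IDs, 2913 with array weights, 746 without MA1 and 808 without MA2.

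Against parental cells, line means gave 1704 higher and 1938 lower genes in xenografts, 2063 higher in subcutaneous and 1819 in lung tumours, and the random block 2287 higher in lung tumours. Without IDs ending in _x_at or _s_at (fewer genes tested) lower genes numbered 1975 in xenografts, 1810 in subcutaneous tumours, 1815 in lung tumours and 877 in all 4 lines. Leaving out the lowest 30% of genes (fewer genes tested) gave 2761 higher in xenografts and 2422 in subcutaneous tumours, and median centring 670 higher in all 4 lines. Without parental arrays 1 to 5 xenografts had 1818 higher, subcutaneous tumours 1637 higher and 1937 lower, lung tumours 1581 higher, and all 4 lines 488 higher and 831 lower. With the RNA quality covariates these were 1895 higher, 1317 and 1736, 1895, and 465 and 860. The 6 odd parental arrays alone gave 1048 higher and 1409 lower in all 4 lines, and the 5 even ones 630 and 1106. Fewer parental arrays alone therefore do not account for the 488 and 831 without arrays 1 to 5. Without the 4 xenografts nearest to the other site 543 were higher in all 4 lines. Leaving out each array gave 666 to 1220 higher in all 4 lines. At least 2-fold, counts were 199 and 316 in xenografts, 168 and 282 in subcutaneous tumours, 240 and 351 in lung tumours, 23 and 7 between sites, 261 among lines, and 92 and 157 in all 4 lines. Lists past the threshold numbered 1 with an estimated correlation and 31 with fry in xenografts, and 1 and 6 between sites.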

Other observations

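Tests of neighbouring genes and of opposed melanoma lists were set beforehand, and the 4 genes of the MA1 subcutaneous tumours were chosen after their values were seen.

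Matrix and adhesion lists did not pass in xenografts against parental cells, with members moving both ways. Of 33 matrix glycoproteins and proteoglycans 15 rose and 7 fell, also adjusted over the list alone (adjusted p = 0.127, adjusted p = 0.513 with an estimated correlation). Of 18 collagens 5 rose and 7 fell, the same adjusted over the list alone (adjusted p = 0.245, adjusted p = 0.614 with an estimated correlation), with a median of 0.00171 and a mean of -0.32. Of 29 matrix proteases and inhibitors 9 rose and 12 fell, with 9 and 13 adjusted over the list alone (adjusted p = 0.301, adjusted p = 0.523 with an estimated correlation), and the median was 0.02 and the mean -0.28. Of 15 integrins 5 rose and 6 fell, the same adjusted over the list alone (adjusted p = 0.3, adjusted p = 0.513 with an estimated correlation). Mesenchymal transition genes gave 5 rises and 7 falls of 16, the same adjusted over the list alone (adjusted p = 0.334, adjusted p = 0.614 with an estimated correlation), with a median of 0.08 and a mean of -0.29. Epithelial adhesion genes gave 3 and 4 of 15, the same adjusted over the list alone (adjusted p = 0.416, adjusted p = 0.523 with an estimated correlation), and metastasis suppressors 5 and 9 of 19, the same adjusted over the list alone (adjusted p = 0.416, adjusted p = 0.513 with an estimated correlation). Angiogenic ligands gave 7 and 9 of 21, the same adjusted over the list alone (adjusted p = 0.161, adjusted p = 0.366 with an estimated correlation), with a median of 0.00214 and a mean of -0.52.

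Rises and falls of the other lists, given first over all genes, were as follows. MRTF-SRF and YAP targets had 2 and 7 of 18 (the same adjusted over the list alone, adjusted p = 0.112, adjusted p = 0.366 with an estimated correlation), DNA replication 3 and 13 of 29 (the same, 0.0573 and 0.614) and MAPK output 5 and 9 of 18 (the same, 0.235 and 0.523). Immediate early genes had 3 and 5 of 17 (the same, 0.444 and 0.729), NRF2 and glutathione genes 4 and 8 of 17 (the same, 0.151 and 0.523), metallothioneins 1 and 2 of 9 (the same, 0.586 and 0.87) and cancer-testis antigens 4 and 6 of 14 (the same, 0.586 and 0.695). Oxidative phosphorylation had 8 and 3 of 27 (5 and 3 alone, 0.846 and 0.94) and cytosolic ribosomal proteins 8 and 5 of 30 (the same, 0.849 and 0.94). Cholesterol synthesis had 5 and 5 of 17 (the same, 0.846 and 0.94, test lower, mean 0.00588), fatty acid synthesis 3 and 1 of 10 (the same, 0.865 and 0.94, test higher, median -0.05) and unfolded protein response genes 11 and 5 of 24 (the same, 0.866 and 0.94). MHC class I genes had 4 and 4 of 13 (the same, 0.91 and 0.961) and MHC class II genes 5 and 3 of 10 (the same, 0.865 and 0.94, test higher, mean -0.05).

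The hypothesis that invasive and melanocyte genes lie on 1 axis within the tumours fitted its test. Across the 21 xenografts Pearson r was -0.635 (permutation p = 0.00211, adjusted 0.00633 over 3 relations) and Spearman rho -0.64 (permutation p = 0.00228), with r -0.552 without the 2 arrays farthest from the median. The lists share 0 genes. Without line MA1, across 16 xenografts, r was -0.541 (permutation p = 0.0335, adjusted 0.0503), rho -0.526 (permutation p = 0.0376) and r without 2 arrays -0.468, so part of the relation may rest on MA1, and tumours of a line are not independent.

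The hypothesis that copy number of chromosome segments shaped the changes against parental cells was not borne out for the xenografts together. The set bar was a value above all 1000 shuffled orders at 50 places. Genes 50 places apart had a Spearman rho of 0.0157 across genes, which 57 of the 1000 reached (highest 0.0239). At 10 places rho was 0.0199, which 14 of 1000 reached, and 1 of 231 windows of neighbouring genes passed. Adjacent genes had 0.0963, above the highest shuffled 0.0311. Of 10 contrasts tested, 10 exceeded all shuffles at 1 place, 3 at 10 places (MA1 against parental cells 0.0391, MA1 against the other lines 0.0601 and MC2 against the other lines 0.0866) and 2 at 50 places. MA2 against parental cells had 0.0242 at 50 places, which 1 of 1000 shuffles reached. For MA1 against parental cells the value at 50 places was 0.0315 (highest shuffled 0.0284) with 5 windows past the limit. For MC2 against the other lines it was 0.0346 (0.0296), so segments that differ in single lines may exist and were not tested further.

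MA1 subcutaneous tumours averaged 9.90 for AIM2, 9.22 for DCSTAMP, 7.84 for LCN2 and 10.83 for TRAF1 on the log2 scale, against at most 8.57, 8.09, 6.65 and 9.74 in any other array. The site effect differed among lines for AIM2 (adjusted p = 3e-04), DCSTAMP (adjusted p = 0.0096) and LCN2 (adjusted p = 3e-04) by limma, and TRAF1 had an adjusted p of 0.21.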
